A study of Mus musculus and Homo sapiens with 198 samples.

How the data were processed

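The material analysed was chromatin immunoprecipitation sequencing (ChIP-seq) of HNF4A, a nuclear receptor that drives much of the hepatocyte gene programme, in livers of male BALB/c mice. The mice received an adenovirus and the livers were taken 24 h later, per the labels' protocols. There were 3 groups of 3 mice: control virus, a virus encoding cyclin D1, and a virus encoding cyclin D1-RD, which the series describes as a truncation mutant. Per the labels cyclin D1 carried FLAG and HA tags, and cyclin D1-RD a FLAG tag. Each library was recorded as 2 sequencing lanes, which were counted as 1 mouse. The numbers in the library names run in a separate block for each virus group, and what they stand for is not given. Any difference that follows this numbering cannot be told apart from the virus. The series also holds 50 RNA libraries of the cell lines AML12, HepG2 and SK-HEP-1 with and without cyclin D1 siRNA, and 9 input libraries; these were not analysed here.

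Each of the 9 deposited files was a list of peaks from 1 library, called alone with HOMER's findPeaks in its transcription factor mode against an input library of its own, per the file headers. The headers give a false discovery rate of 0.01, at least 4-fold more tags than input and than the surrounding 10 kb, and a Poisson p of 0.0001 for each of these filters. The build was mm9, as the tag directory names in the headers and the submitters' processing notes have it. Those notes also name Bowtie 0.12.7, bcl2fastq 2.17.1.14, HOMER, edgeR and DiffBind without saying which step each served. How the lanes of a library were joined is not given in the sources used here. The peak width was fixed within a library, between 139 and 155 bp, and each peak was centred on its highest pile-up.

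Per the file headers, the normalised tag count of a peak is a signal scaled to 10000000 tags per library, with at most 1 tag counted per base position. The deposited findPeaks score is the capped number of tags at the peak before that scaling. The deposited total tags are whole counts without the cap, and the control tags are the scaled input signal, both as the authors' peak caller wrote them. The deposited fold over input is the ratio of these 2 values; it was used only to describe each list. The headers also give each library's total tags, from 11116792 to 21765618, and the IP efficiency, which is the percentage of all tags that lie in peaks. No column of the lists was left without a sample.

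Peaks of the 9 lists were merged into sites where they overlapped by at least 1 bp, and a site counted as called in a library when 1 of that library's peaks lay in it. Where a site held more than 1 peak of a library, which was so for 0.0144% of site and library pairs, the highest value was taken. A reproducible site was one called in at least 2 of the 3 mice of a group. A list gives no value where no peak was called, so tag density was compared only at sites called in all 9 libraries, called shared sites below. This selection leaves out sites that were lost from the list of any mouse. Numbers of peaks, IP efficiency and the mean log2 density of each mouse were compared by two-sided exact permutation tests with Benjamini-Hochberg adjustment over the 3 pairs of groups. With 3 mice against 3 the smallest p such a test can give is 0.1. Density at shared sites was tested as log2(normalised tags + 1) with limma 3.58.1, a group-means design over the 9 libraries and a trended prior, with Benjamini-Hochberg adjustment within each contrast and a threshold of 0.05. Fold changes are therefore on that log2 scale, which understates changes at weak sites. In the main fit the SE and p of a site rest on the spread pooled over sites of like density. They hardly depend on the spread of the mice at that site. Shifts of whole libraries are common to all sites, so the sites called in a contrast are not independent. No further scaling was applied in the main test, so a factor that acts on a whole library stays in the fold changes; median-centred values, in which each library's median over shared sites is subtracted, show changes relative to the median site.

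The lists held both the normalised values for which the limma test was planned and whole tag counts. The counts were tested as alternatives with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0, with each library's total tags as its size. The other alternatives, fixed with the tests, were quantile normalisation, pseudocounts of 0.1 and 5, only the denser sites, other site sets, a replicate block, stricter peak thresholds, lists of equal length, other overlap and merging rules, and leaving out each mouse in turn. For sites called in at least 2 of 3 mice of either group, each uncalled value was set to the lowest density of that list. Fits of all 6 libraries of 2 groups, and fits without 1 mouse, took the sites called in all libraries required, a larger set than the shared sites. Fits with library covariates, with input subtracted, with uncapped tags, with factors estimated over shared sites, with values centred within 20 bins of mean density and with peaks merged within 500 bp were added after the data had been seen. Computation used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

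The groups, the tests, the alternatives and the rule for named sites were fixed before the data were examined. The rule names, for each contrast and direction, up to 10 sites with the largest fold change among those past the threshold whose values did not overlap between the 2 groups. Where none passed, it names the 5 sites with the smallest p in each direction, given as values and not as changes. It also names the 5 sites with the highest mean density over the 9 libraries, and for each pair and direction the 5 densest sites called in 3 of 3 mice of one group and 0 of 3 of the other. Sites are given by mm9 coordinates alone, because an mm9 gene annotation was not used here. For the same reason the planned tests of gene lists, of binding near listed genes and of the genomic location of sites were not made.

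The limma procedure was tested on simulated data for cyclin D1 against control, with 200 changed sites among 19921 and the real means and spreads. Without library offsets it recovered 0% of sites changed by 0.5 on the log2 scale, 32% of those changed by 1, 86% by 1.5 and 98% by 2, with 9 false calls. With library offsets of the observed size it recovered 0%, 30%, 96% and 100% on uncentred values and 24%, 88%, 100% and 100% on median-centred values, with 0 and 17 false calls. The 0 false calls cannot be carried over to offsets that part the compared groups. In the real data a split of the cyclin D1 and cyclin D1-RD mice by overall density called 6439 sites on uncentred values. On simulated counts for the same comparison and number of sites edgeR recovered 0%, 24%, 80% and 96%, with 4 false calls. The count of sites called in one group alone recovered 200 of 200 planted sites.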

Results

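HNF4A binding was profiled by ChIP-seq in the livers of 9 male BALB/c mice, 3 each with a control adenovirus, an adenovirus encoding cyclin D1 and one encoding the truncation mutant cyclin D1-RD. Cyclin D1 is a regulatory subunit of the kinases that take cells from G1 into S phase. The series asks how cyclin D1 and HNF4A, a regulator of liver metabolism, act on each other, and this experiment asks where HNF4A sits in the genome when cyclin D1 is raised. Total tags were 16913098, 15476459 and 18587399 in the control mice, 19643904, 21765618 and 11116792 with cyclin D1, and 13726583, 17588379 and 14737123 with cyclin D1-RD. Densities are given as normalised tags, scaled to 10000000 tags per library. The 9 lists held 438980 peaks, which merged into 105042 sites with a median width of 178 bp. Of these, 19921 were called in all 9 libraries and 38285 in 1 library only.

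Among the sites called in all 9 mice, the highest mean density lay on chromosome 1, 90184720 to 90184894, with 177 ± 13.4 normalised tags (SD, n = 3) in control mice, 158 ± 28.2 with cyclin D1 and 179 ± 13.7 with cyclin D1-RD. Next came chromosome 11, 3061381 to 3061557, with a mean over the 9 libraries of 166.6, and chromosome 16, 76454125 to 76454314, with 148. The remaining 2 were chromosome 11, 3046733 to 3046898, at 136, and chromosome 2, 167390553 to 167390727, at 134. The 2 sites on chromosome 11 also carried strong input signal, with means of 73.4 and 50.6 scaled input tags against 15.6, 3.50 and 3.98 at the other 3. Only the site on chromosome 2 passed the threshold in a contrast, with 111 ± 7.94 with cyclin D1 against 148 ± 7.21 in control mice (limma, adjusted p = 0.0162, log2 fold change -0.42 ± 0.14 SE). Counting 1 tag per position sets a ceiling on these values, taken here as the peak width times 2 strands. The cap acts before scaling, so in normalised tags the ceiling is lower in libraries with more total tags. The highest normalised count in a list was 138.2 for cyclin D1 replicate 2 (21765618 tags) and 254.2 for replicate 3 (11116792 tags). Means and SD at the densest sites therefore depend partly on total tags. The chromosome 1 site reached between 75.2% and 100.3% of the ceiling in the 9 libraries, so this ceiling is approximate. The chromosome 2 site reached between 41.0% and 86.9%. Without that cap the chromosome 1 site held 459 ± 68.3 scaled tags in control mice, 287 ± 39.2 with cyclin D1 and 355 ± 30.7 with cyclin D1-RD (SD, n = 3). Uncapped means at chromosome 11, 3046733, were 261, 239 and 300 in the same order of groups. At chromosome 16, 76454125, they were 258, 182 and 216, so the order of these 2 sites depends on the cap. At 19 shared sites (0.0954%) a library reached at least 80% of the ceiling.

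Fewer sites were reproducible in mice with raised cyclin D1, but the mice of a group differed widely. Sites called in at least 2 of 3 mice numbered 50891 with control virus, 38046 with cyclin D1 and 43350 with cyclin D1-RD, and 31315 were reproducible in all 3 groups. Of the reproducible control sites, 66.9% were also reproducible with cyclin D1 and 75.5% with cyclin D1-RD. Of the reproducible cyclin D1 sites, 89.4% were also reproducible with control virus. The lists held 54802 ± 890 peaks in control mice, 43378 ± 11601 with cyclin D1 and 48146 ± 6049 with cyclin D1-RD (SD, n = 3). The differences from control of -11424 and -6656 peaks gave exact permutation p of 0.4 and 0.3 (adjusted p = 0.6 for both). With peak thresholds 2 and 4 times the highest of the lists' minimum values the exact permutation p was 0.1 at both for cyclin D1, and 0.2 and 0.1 for cyclin D1-RD. Leaving out replicate 2 of each group moved the differences to -18107 and -10083.5 (exact permutation p = 0.1 for both), and leaving out cyclin D1-RD replicate 1 moved the second to -4362.5 (exact permutation p = 0.3). The difference between cyclin D1 and cyclin D1-RD of -4768 peaks gave an exact permutation p of 0.6; it was -1811, -11451 and -1042 without cyclin D1 replicates 1, 2 and 3 and -1340 without cyclin D1-RD replicate 2. The share of tags in peaks was 14.2% ± 0.731 in control mice, 8.96% ± 3.20 with cyclin D1 and 10.8% ± 2.19 with cyclin D1-RD (SD, n = 3). All 3 mice of each cyclin D1 group lay below all 3 control mice, which gave the smallest p that 3 against 3 allow (exact permutation test, p = 0.1, adjusted p = 0.15). With the share taken as the sum of normalised tags over called peaks, the exact permutation p was 0.1 for cyclin D1 and 0.2 for cyclin D1-RD. Replicate 2 of both groups stood apart from the other mice of its group, with 12.64% and 13.25% of tags in peaks and lists as long as those of control mice.

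**Figure D1:**
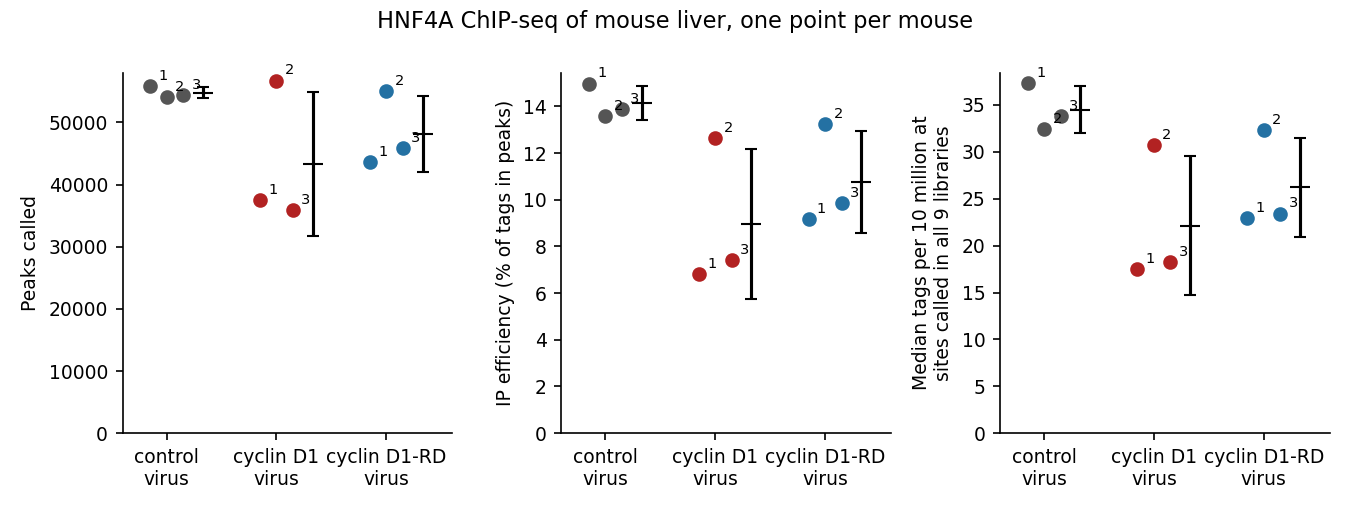
Peaks called (left), percentage of tags in peaks (centre) and median normalised tags at sites called in all 9 libraries (right) for each mouse of the 3 virus groups. Points are mice with their replicate number, and the bar and whiskers are mean ± SD (n = 3); replicate 2 of the cyclin D1 group has 56745 peaks while the other 2 mice have 37464 and 35926.

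With cyclin D1, HNF4A density fell at a large part of the shared sites. Of 19921 sites, 7751 (38.9%) were lower and 90 (0.452%) higher than with control virus (limma, adjusted p under the threshold of 0.05). The median log2 fold change was -0.63, a density 0.646 times that of control, and 93.3% of sites had a negative value. Median densities of the single mice were 37.3, 32.4 and 33.8 normalised tags with control virus and 17.5, 30.7 and 18.2 with cyclin D1. All 3 cyclin D1 mice lay below the control mice in mean log2 density (4.53 ± 0.41 against 5.13 ± 0.09, SD, n = 3), with an exact permutation p of 0.1, the smallest possible, and an adjusted p of 0.3. The IP efficiency of the libraries moved in the same direction, as given above.

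The site that fell most lay on chromosome 1, 135225825 to 135226014, where density was 73.0 ± 10.3 with control virus and 17.7 ± 12.2 with cyclin D1 (SD, n = 3). Its log2 fold change was -2.16 ± 0.33 (SE; limma, adjusted p = 6.74e-07), which is 0.223 times the control level. It held 31.6 ± 9.67 with cyclin D1-RD. The p of this site rests on a spread pooled over sites of like density, and hardly on that of its own mice. Sites on chromosome 4, 26314065 to 26314257, and chromosome 9, 120893727 to 120893969, had log2 fold changes of -1.96, and chromosome 14, 61267910 to 61268093, and chromosome 13, 28200481 to 28200697, of -1.95. The other 5 of the 10 largest falls were on chromosome 16, 35472373 to 35472573, chromosome 13, 37550550 to 37550740, chromosome 9, 63381286 to 63381469, chromosome 11, 77177986 to 77178188, and chromosome 17, 47440662 to 47440839. Their log2 fold changes lay between -1.90 and -1.88. At chromosome 9, 63381286, density was 66.8 ± 2.21 with control virus, 18.6 ± 8.71 with cyclin D1 and 48.1 ± 15.2 with cyclin D1-RD. All 10 were also lower relative to the median site (limma on median-centred values, adjusted p at most 0.000143). With IP efficiency as a covariate the site on chromosome 9, 63381286, still passed the threshold and the other 9 did not. That covariate moved the fold changes upwards over the shared sites as a whole, which makes falls smaller.

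A smaller set of sites rose with cyclin D1. The largest rise was on chromosome 12, 84225023 to 84225231, from 8.77 ± 0.208 to 32.2 ± 6.51 normalised tags (SD, n = 3), 3.36 times the control level (log2 fold change 1.75 ± 0.34 SE; limma, adjusted p = 9.74e-05). On chromosome 13, 113031617 to 113031808, density was 13.6 ± 5.78 with control virus and 42.6 ± 9.54 with cyclin D1. Rises of 2.82-fold on chromosome 5, 142995921 to 142996176, 2.81-fold on chromosome 3, 110382229 to 110382572, and 2.75-fold on chromosome 9, 102647743 to 102647933, followed. The other 5 were on chromosome 19, 5518775 to 5518978, chromosome 10, 26715791 to 26716071, and chromosome 3, 107828308 to 107828534, 135162040 to 135162235 and 27588555 to 27588747, with rises between 2.57-fold and 2.64-fold. The 10 sites had control densities of 6.30 to 13.6, below the control median of every mouse. With IP efficiency as a covariate 9 of these 10 still passed the threshold, and the site on chromosome 3, 27588555, did not. Because that covariate moved the fold changes upwards over the shared sites as a whole, it favours rises over falls. The 9 sites kept therefore do not separate these rises from IP efficiency. The number of higher sites was 20, 37 and 37 without control replicates 1, 2 and 3, and 67, 74 and 33 without cyclin D1 replicates 1, 2 and 3.

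**Figure D2:**
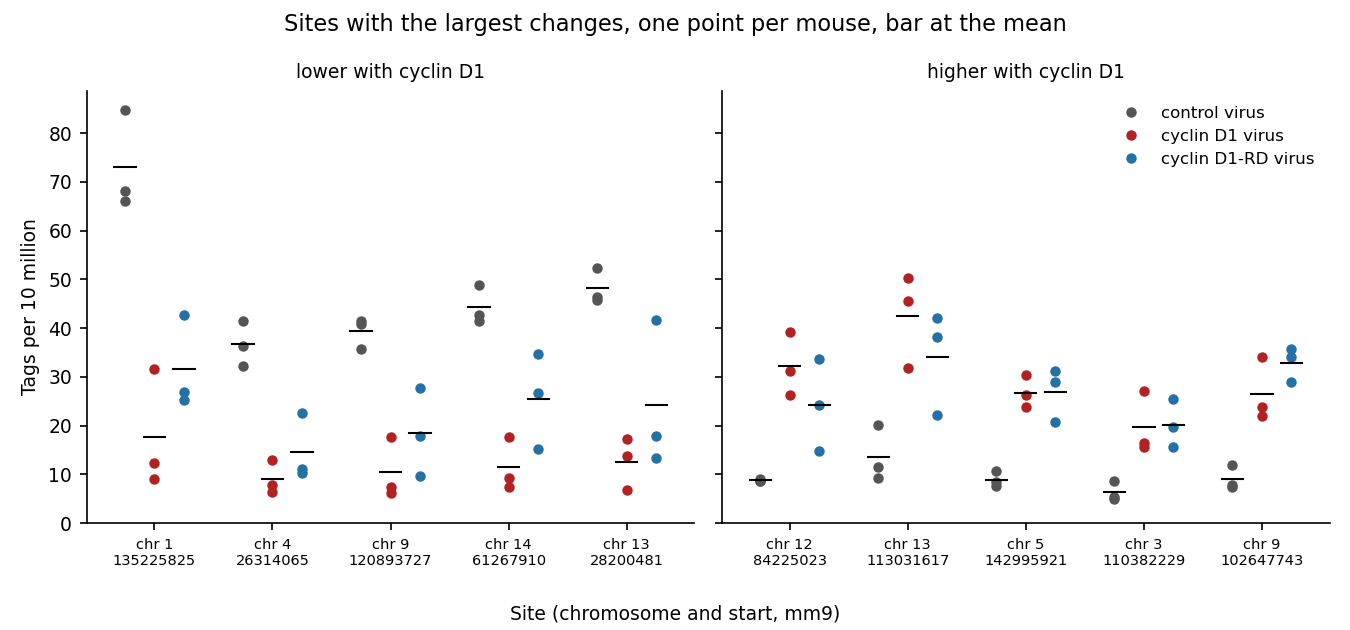
Normalised tags (vertical axis) at the 5 sites with the largest fall (left) and the 5 with the largest rise (right) with cyclin D1, for the 3 mice of each virus group. Points are mice and the bar is their mean; at the first site on the left all 3 cyclin D1 mice lie below all 3 control mice, with means of 17.7 and 73.0.

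The split between falls and rises depended on the scaling. Relative to the median site, 912 sites were lower and 1513 higher with cyclin D1 (limma on median-centred values), so that lower sites made up 37.6% of the calls and not 98.9%. Relative to sites of like density, in 20 bins, 826 were lower and 1212 higher. Of the 7841 sites called without centring, 1002 were called in the same direction with it. On whole tag counts edgeR called 5136 lower and 83 higher, and limma with IP efficiency as a covariate 28 and 87. Leaving out single mice moved the number of lower sites from 7751 to 15127 without cyclin D1 replicate 2, to 1823 and 1469 without cyclin D1 replicates 1 and 3, and to 1049, 3435 and 2708 without control replicates 1, 2 and 3. Each of these fits took the sites called in all remaining libraries, a larger set than the shared sites, so the counts have different bases.

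With the truncation mutant cyclin D1-RD, 43 shared sites (0.216%) were lower and 9 (0.0452%) higher than with control virus (limma). The median log2 fold change was -0.38, a density 0.768 times that of control, and 89.0% of sites had a negative value. Mean log2 density was 4.77 ± 0.26 against 5.13 ± 0.09 in control mice (SD, n = 3; exact permutation p = 0.2, adjusted p = 0.3), so the exact test did not separate the difference from the spread between mice. The largest fall was on chromosome 12, 85391724 to 85391901, from 54.8 ± 7.90 to 16.2 ± 6.53 (log2 fold change -1.75 ± 0.34 SE; limma, adjusted p = 0.00324), and this site held 15.8 ± 1.72 with cyclin D1. A nearby site on the same chromosome, 85351220 to 85351420, fell by 1.56 on the log2 scale. Sites on chromosome 9, 65039797 to 65040050, chromosome 12, 55560755 to 55561074, and chromosome 10, 127636652 to 127636867, had log2 fold changes of -1.60, -1.53 and -1.52. The other 5 of the 10 largest falls lay on chromosome 1, 162770886 to 162771093, chromosome 3, 28580999 to 28581232, chromosome 19, 43600500 to 43600686, chromosome 9, 31015348 to 31015593, and chromosome 13, 37736806 to 37737019. Their log2 fold changes were between -1.52 and -1.49.

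The largest of the 9 rises with cyclin D1-RD was on chromosome 9, 102647743 to 102647933, from 9.03 ± 2.58 to 32.9 ± 3.58 normalised tags (SD, n = 3), 3.44 times the control level (limma, adjusted p = 0.00324). Chromosome 9, 20768725 to 20768895, rose 3.31-fold. The sites on chromosome 3, 110382229 to 110382572, and chromosome 5, 142995921 to 142996176, rose 2.92-fold and 2.81-fold, and both were also among the 10 largest rises with cyclin D1. Chromosome 18, 9487342 to 9487520, was the densest of the 9, with 28.0 ± 3.04 in control mice and 72.2 ± 22.1 with cyclin D1-RD. The remaining 4 were chromosome 1, 127436004 to 127436173, chromosome 13, 113842691 to 113843056, chromosome X, 68276132 to 68276336, and chromosome 2, 157305732 to 157305901, with rises between 2.30-fold and 2.66-fold.

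These counts also moved with the fit. Relative to the median site 222 sites were lower and 542 higher with cyclin D1-RD (limma on median-centred values), so that lower sites made up 29.1% and not 82.7% of the calls, and relative to sites of like density 202 were lower and 460 higher. With only these 2 groups in the fit 2391 were lower and 62 higher, and edgeR on whole tag counts called 24 lower and 7 higher. Leaving out replicate 2 of the cyclin D1-RD mice gave 960 lower sites and 14 higher. Leaving out control replicate 1 gave 0 and 0, control replicate 2 gave 1 and 2, and control replicate 3 gave 0 and 2. Leaving out cyclin D1-RD replicate 1 gave 1 and 4, and replicate 3 gave 0 and 1.

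**Figure D3:**
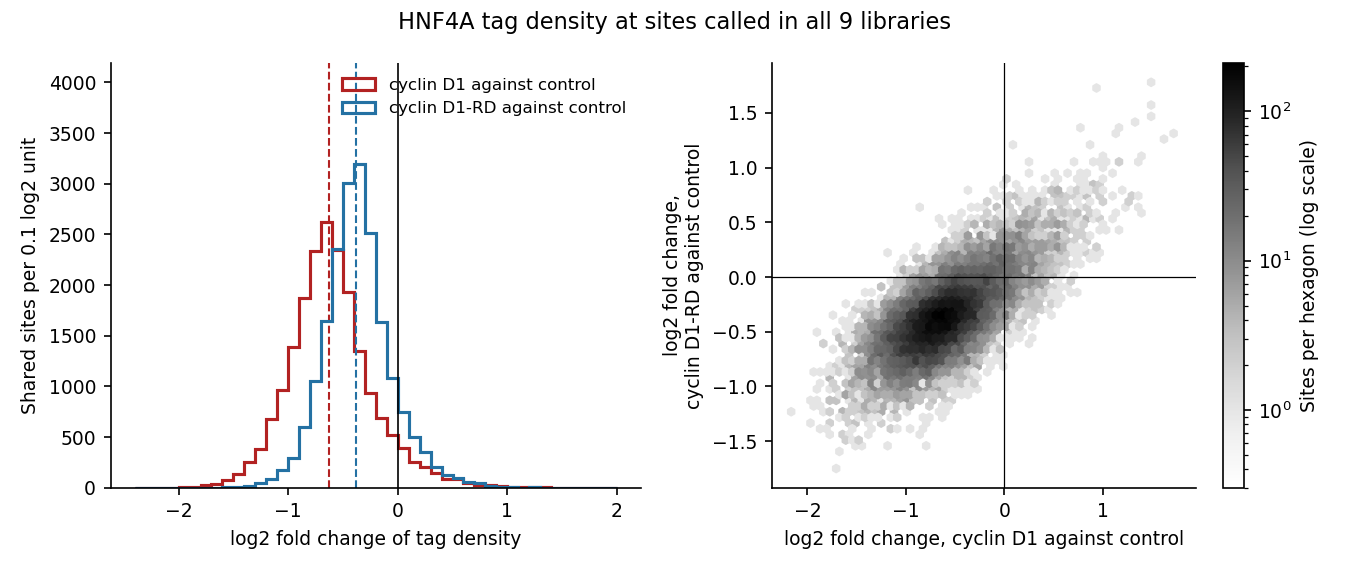
Left, number of shared sites (vertical axis) by log2 fold change of tag density (horizontal axis) for cyclin D1 and cyclin D1-RD against control virus, with dashed lines at the medians of -0.63 and -0.38. Right, the same fold changes of each site for the 2 viruses, shaded by the number of sites on a log scale; both changes use the same 3 control libraries, and their correlation across sites is 0.70.

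The fold changes with the 2 viruses shared their direction at many sites, but both were taken against the same 3 control libraries. Their correlation over 19921 sites, which are not independent replicates, was 0.70, and 33 of 100 simulated draws of unchanged groups with shared controls gave as large a value, with a mean of 0.46. Relative to the median site, 420 sites were higher with both viruses and 122 lower with both. Equally long lists from the simulated unchanged groups shared 217 and 84.0 sites on average, and 16 and 31 of the 100 draws shared as many. The covariance was 0.0846 against a simulated mean of 0.0197, and 1 of 100 draws reached it. A response common to both viruses was therefore not separated from the shared controls by the correlation or by the overlap.

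Cyclin D1 and cyclin D1-RD were also compared directly. The 2 forms differ in their tags as well as in the truncation, and their library numbers run in separate blocks. These differences cannot be told apart. No shared site passed the threshold in limma (0 lower, 0 higher), while 1769 were lower and 44 higher at an unadjusted p under 0.05. On whole tag counts edgeR and DESeq2 also called 0, with 1051 and 1118 lower and 55 and 32 higher at an unadjusted p under 0.05. The median log2 fold change was -0.24, and mean log2 density did not differ by more than the spread between mice (exact permutation p = 0.5). Leaving out cyclin D1 replicate 2 gave 5211 lower sites and 1 higher. Relative to the median site, 160 were lower with cyclin D1 and 89 higher (limma on median-centred values). Relative to sites of like density, in 20 bins, 140 were lower and 71 higher (limma); edgeR with TMM factors called 137 and 70, and DESeq2 with median-of-ratios factors 6 and 0 (788 and 618 at an unadjusted p under 0.05). The sites with the smallest p for lower values lay on chromosome 9, 63381286 to 63381469, chromosome 5, 28599457 to 28599688, chromosome 19, 31965552 to 31965739, chromosome 7, 142949974 to 142950155, and chromosome 5, 137138760 to 137138934. The first of them held 18.6 ± 8.71 with cyclin D1 and 48.1 ± 15.2 with cyclin D1-RD (SD, n = 3; limma, adjusted p = 0.111). The site on chromosome 5, 28599457, held 12.0 ± 6.54 and 33.1 ± 3.83, with 21.3 ± 4.45 in control mice. For higher values they lay on chromosome 13, 52144256 to 52144508, chromosome 2, 68698499 to 68698711, chromosome 16, 92234852 to 92235242, chromosome 6, 94067096 to 94067306, and chromosome 19, 5518775 to 5518978 (limma, adjusted p between 0.457 and 0.469). On median-centred values all 10 sites passed the threshold (limma, adjusted p between 0.000444 and 0.0256), and centred within the 20 bins 8 of the 10 did.

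Some sites were called in every mouse of one group and in no mouse of another. There were 2040 such sites with control virus and not cyclin D1, and 363 with cyclin D1 and not control virus. Against cyclin D1-RD, 1335 sites were called with control virus alone and 365 with cyclin D1-RD alone. Between the 2 cyclin D1 forms, 191 sites were called with cyclin D1 alone and 513 with cyclin D1-RD alone. A single site cannot pass an exact test at 3 mice against 3. Counted over the mice that remain, leaving out cyclin D1 replicate 2 gave 7190 control sites absent with cyclin D1, and leaving out control replicates 1, 2 and 3 gave 3140, 3872 and 3357. Cyclin D1 sites absent with control virus numbered 916 and 1086 without cyclin D1 replicates 1 and 3, and 586 without control replicate 3. Between cyclin D1-RD and control virus, control sites numbered 3851 without cyclin D1-RD replicate 2 and 2219, 2841 and 2482 without control replicates 1, 2 and 3, and cyclin D1-RD sites numbered 1156, 688 and 882 without cyclin D1-RD replicates 1, 2 and 3 and 603, 591 and 694 without control replicates 1, 2 and 3. Between the cyclin D1 forms, cyclin D1 sites numbered 733, 313 and 885 without cyclin D1 replicates 1, 2 and 3 and 634 and 392 without cyclin D1-RD replicates 2 and 3. The reverse count was 2956 without cyclin D1 replicate 2, and 1559, 870 and 1421 without cyclin D1-RD replicates 1, 2 and 3. With lists of equal length the counts were 1162 and 870 for control virus against cyclin D1, 676 and 618 against cyclin D1-RD, and 333 for cyclin D1 alone against cyclin D1-RD.

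These sites were mostly weak. The median density of the 2040 control sites absent with cyclin D1 was 10.4 normalised tags, against 21.5 for the 37834 sites called in all 3 control mice. The densest of them lay on chromosome 10, 95236136 to 95236312, with 68.1 ± 11.02 (SD, n = 3), a site that all 3 cyclin D1-RD mice also had, and chromosome 10, 76035075 to 76035241, with 67.1 ± 4.56. Chromosome 5, 139847920 to 139848140, chromosome 9, 63897606 to 63897790, and chromosome 4, 59344462 to 59344630, held 53.7 ± 9.45, 52.8 ± 6.40 and 50.3 ± 11.04. The densest sites called with cyclin D1 and not control virus were on chromosome 14, 69793158 to 69793340, with 41.3 ± 8.75, and chromosome 5, 124457004 to 124457184, with 37.9 ± 6.56. Chromosome 3, 103018919 to 103019077, chromosome 11, 4011678 to 4011857, and chromosome 12, 110091119 to 110091281, followed with 34.6 ± 12.0, 31.1 ± 5.59 and 29.3 ± 9.72. Of these sets of 5, 3 and 4 had a peak centre of the other group within 500 bp, against 13.8% of the 2040 and 14.6% of the 363 sites.

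With cyclin D1-RD and not control virus, the densest sites were on chromosome 3, 103018919 to 103019077, with 44.2 ± 12.4 (SD, n = 3), chromosome 11, 102269257 to 102269414, chromosome 8, 119851585 to 119851738, chromosome 2, 152565182 to 152565364, and chromosome 3, 134951182 to 134951358. In the reverse direction they were on chromosome 8, 95722136 to 95722302, with 61.5 ± 13.2, chromosome 4, 45426439 to 45426630, chromosome 3, 103018613 to 103018782, chromosome 3, 52405451 to 52405665, and chromosome 11, 4016836 to 4017012. Between the cyclin D1 forms, the densest sites with cyclin D1 alone were on chromosome 5, 66444151 to 66444323, with 47.0 ± 14.7, chromosome 10, 88921613 to 88921784, chromosome 7, 4102565 to 4102723, chromosome 9, 63897346 to 63897504, and chromosome 3, 104403794 to 104403988. With cyclin D1-RD alone they were a mitochondrial peak, 11053 to 11208, with 195 ± 24.7, then chromosome 5, 66443976 to 66444138, chromosome 10, 95236136 to 95236312, chromosome 1, 93336812 to 93336982, and chromosome 10, 88921830 to 88922023. A peak centre of the other group lay within 500 bp of 5 and 4 of these sets of 5 for cyclin D1-RD against control virus, and of 5 and 4 between the cyclin D1 forms. Over all such sites the shares were 26.0% and 15.7%, and 20.9% and 21.8%. Some opposing lists name neighbouring sites. Against control virus these were chromosome 3, 103018919 and 103018613. Between the cyclin D1 forms they were chromosome 5, 66444151 and 66443976, and chromosome 10, 88921613 and 88921830. At these, a displaced peak centre was not told apart from a gain or loss of a site.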

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

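The tests of IP efficiency on overall density, of centring within bins of density, of input subtraction, of list length, of displaced peak centres and of other splits of the mice were chosen only after the results they bear on were seen, and the fits with covariates were added after the data had been seen, with bounds set before their values were.

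The direct comparison of the 2 cyclin D1 forms drew attention because relative binding differed between them in a test of the difference itself: 249 sites on median-centred values, 160 lower and 89 higher with cyclin D1 (limma), against 0 on uncentred values (unadjusted 1769 and 44; edgeR and DESeq2 on total tags also 0). Centred within 20 bins of mean density, 140 were lower and 71 higher (limma), and the median change of the 249 sites was 0.77 (median SE 0.18) before and 0.76 (median SE 0.19) after. Quantile normalisation gave 188 lower and 89 higher, edgeR with TMM factors 137 and 70, and input subtraction with median-centring 177 and 80. DESeq2 with median-of-ratios factors called only 6 lower and 0 higher. An IP efficiency covariate in limma also left fewer sites than median-centring did, as given below. Uncentred, the count of 0 makes each of the 10 splits of these 6 mice as large, 10 of 10, and says nothing of chance. The highest other split, cyclin D1 replicates 1 and 3 with cyclin D1-RD replicate 1 against the rest, gave 6439. That split parts mice by overall density and not by virus, which points to a structure of the samples. On centred values 1 of 10 splits, the real one, reached 249, and the highest other split gave 3; 10 splits are too few for a share under 0.05.

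The first pattern is the lower density over shared sites with cyclin D1. Fewer sequenced tags stay open: with total tags as a covariate the median log2 fold change kept 0.991 times its size, but the SD of that ratio over fits with 1 library left out was 0.258, with a range of 0.824 to 1.72, so the bound of 0.8 was not passed by more than its spread, although the mean of total tags was 1.03 times that of control mice and 10021 sites were lower with the covariate. A library-wide difference in immunoprecipitation efficiency cannot be told apart from less HNF4A on chromatin, because efficiency is calculated from the same tags and moved with the groups, and as a covariate it took the median log2 fold change from -0.63 to -0.015. The 3 cyclin D1 mice spanned 0.73 in mean log2 density, more in size than the difference of -0.61 between the group means. A factor of the needed size therefore varied among the mice with cyclin D1. The 3 control mice spanned 0.18, and the cyclin D1-RD mice lay between 4.60 and 5.07. Less bound HNF4A with cyclin D1 stays open as the biological explanation; for the 7841 sites past the threshold, 1 of 10 splits reached that number and the highest other gave 0, with too few splits for a share under 0.05.

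The second pattern is the change of sites relative to the median site, 2425 with cyclin D1 (912 lower and 1513 higher). A larger background share in libraries of low efficiency stays open for part of them. With each library centred within 20 bins of mean density 76.7% were called in the same direction (SD 2.53 percentage points with 1 library left out). The median change was 0.76 before and 0.68 after, with a median SE of 0.21 for both. After subtraction of input 90.5% were called in the same direction. The weakest of 4 bins of sites held 642 higher and 46 lower, the strongest 180 and 284. A site had to be called in every mouse to count, so weak sites that fell below a list's limit are missing from these numbers. IP efficiency itself stays open: as a covariate it left 0.817 times the median relative change (SD 0.0186 with 1 library left out, which does not clear the bound of 0.8), from 0.76 to 0.62 with a median SE of 0.21 and 0.31, so that the change was smaller and its errors wider, and 122 of the sites were still called. A change of preferred sites with cyclin D1 stays open as a hypothesis; of the 10 splits 1 gave as many sites on centred values and the highest other gave 0, too few splits for a share under 0.05.

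The third pattern is the excess of sites called with control virus alone. Longer control lists and less binding cannot be told apart, since list length itself follows the signal: the ratio of control-only to cyclin D1-only sites was 5.62 with full lists, 1.34 with lists of equal length, and 15.9 and 53.9 with common thresholds 2 and 4 times the highest of the lists' minimum values. Displaced peak centres are argued against as the main source, since 13.8% of the control-only sites had a cyclin D1 peak centre within 500 bp, although 3 of the 5 densest did. In both directions together there were 2403 sites, reached by 1 of 10 splits, and the highest other gave 1798; such splits are too few for a share under 0.05. Less HNF4A binding stays open for the whole excess.

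For cyclin D1-RD against control virus, 1 of 10 splits, the real one, gave 52 sites on uncentred values and 764 on centred values, with a highest other of 0 for both. For sites called in one group alone it was 1 of 10 with 1700 sites and a highest other of 1203, and between the 2 cyclin D1 forms 4 of 10 with 704 sites and a highest other of 2052. These splits too are too few for a share under 0.05.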

How the results depend on the processing

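The count models with factors over shared sites, the density-bin centring, the input-subtracted, uncapped and covariate fits and the 500 bp merging were chosen only after the data had been seen. With IP efficiency as a covariate the median log2 fold changes shrank to -0.015 for cyclin D1 and -0.024 for cyclin D1-RD against control, and cyclin D1 against cyclin D1-RD gave 0.015; in the other fits that give a median, all 3 stayed negative. Centred and quantile-normalised values fix that median and give no value for it. The planned gene-list, listed-gene and genomic-location tests were not run for want of an mm9 annotation. Replicate numbers did not pair the mice. Below, counts of shared sites are higher/lower. The cause of each shift was not tested.

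For cyclin D1 against control, against 90/7751, median-centring gave 1513/912, quantile normalisation 1099/1002, input subtraction with centring 1456/955, edgeR with TMM 1499/1261, DESeq2 with median-of-ratios factors 663/413, and edgeR on total tags 5136 lower. Centring within 20 bins of density gave 1212/826, an IP efficiency covariate 28 lower, the denser sites 17 higher, and sites called in 2 of 3 mice of either group 546 higher. For cyclin D1-RD against control, against 9/43, the same first 5 settings gave 542/222, 328/164, 499/211, 640/395 and 172 higher; edgeR and DESeq2 on total tags gave 24 lower each. Centring within density bins gave 460/202, an IP efficiency covariate 95/16, total tags as a covariate 14 higher, the denser sites 1/4, 2 of 3 mice 71/405, all 6 libraries 74/2984, a replicate block 16/234, only these groups 62/2391, no trend 17/231 and pseudocount 5 102 lower. For cyclin D1 against cyclin D1-RD, against 0/0 (limma; unadjusted 44/1769; edgeR and DESeq2 0 on total tags), they gave 89/160, 89/188, 80/177, 70/137 and 6 lower; centring within density bins gave 71/140, 2 of 3 mice 5/27, a replicate block 16 lower, no trend 5 lower, an IP efficiency covariate 20 lower and total tags as a covariate 231 lower.

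With peak thresholds 2 and 4 times the highest of the lists' minimum values, sites called with cyclin D1 and not control numbered 139 and 33 (the reverse 2208 and 1780), with cyclin D1-RD and not control 180 and 31 (the reverse 1273 and 1038), with cyclin D1 and not cyclin D1-RD 66 and 7, and the reverse 276 and 83. At 4 times, the shares of reproducible control sites also found with cyclin D1 and cyclin D1-RD were 40.9% and 61.9%, and of cyclin D1-RD sites with cyclin D1 61.5%. Lists of equal length gave 870 and 1162 for cyclin D1 and control, 618 and 676 for cyclin D1-RD and control, and 333 for cyclin D1 and not cyclin D1-RD.

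With 1 mouse left out, a group of 2 was assumed to vary like the others, and density was tested at all sites called in the remaining libraries. Cyclin D1 against control gave 20 to 74 higher, 1049 to 15127 lower and medians of -0.86 to -0.50. Cyclin D1-RD against control gave 0 to 14, 0 to 960 and -0.52 to -0.30, and cyclin D1 against cyclin D1-RD 0 to 1, 0 to 5211 and -0.48 to -0.098. Sites called in one group alone ranged from 530 to 1086 (cyclin D1, not control), 2326 to 7190 (the reverse), 591 to 1156 (cyclin D1-RD, not control), 1771 to 3851 (the reverse), 283 to 885 (cyclin D1, not cyclin D1-RD) and 647 to 2956 (the reverse). The shares of reproducible sites ranged from 45.8% to 75.3%, 58.5% to 83.5% and 53.7% to 86.8%, and the covariance excess from 0.0545 to 0.0704. Of the named sites, 86 of the values for cyclin D1-RD against control and 1 for cyclin D1 against control lost the threshold; with IP efficiency as a covariate 10 of the 20 sites named for cyclin D1 against control lost it, and 2 of the 19 for cyclin D1-RD.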

Other observations

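The windows of neighbouring sites below, their shuffles and the comparison by site strength were chosen only after the values were seen.

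Some windows of 100 kb held several sites that changed relative to the median site with cyclin D1. On chromosome 8, between 109900001 and 110000000, 4 of 5 shared sites were higher with cyclin D1 (limma on median-centred values), and 4 with cyclin D1-RD. On chromosome 9, between 66100001 and 66200000, 4 of 4 were higher with cyclin D1 and 2 with cyclin D1-RD. Other windows held at most 3 higher sites; the first 3 listed of these, on chromosomes 10, 12 and 13, had 1, 1 and 0 for cyclin D1-RD. Among lower sites, chromosome 12, 25900001 to 26000000, held 4 of 9, against 0 with cyclin D1-RD, although the median relative log2 fold changes of the window were -0.34 and -0.32 and their difference was not tested. The next 3, on chromosomes 12, 14 and 6, held 3 each, with 0, 1 and 3 for cyclin D1-RD. With the calls shuffled over the shared sites, 75 and 19 of 100 shuffles had a window with as many higher or lower sites. Windows with at least 3 higher sites numbered 22 against a mean of 12.7, reached by 0 of 100 shuffles, and with at least 3 lower sites 4 against 3.16, reached by 39. In 4 equal bins of mean density, from the weakest sites to the strongest, the median log2 fold changes with cyclin D1 were -0.45, -0.65, -0.71 and -0.66. Sites that fell below a list's limit in any mouse are absent from these bins.

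Sites in clusters may respond differently from isolated ones. The 2197 shared sites with at least 3 other shared sites within the distance commonly used to stitch enhancers exceeded the 8327 with none by 0.44 ± 0.02 in mean log2 density in control mice, 0.32 ± 0.01 with cyclin D1 and 0.35 ± 0.01 with cyclin D1-RD (SD, n = 3). The difference between cyclin D1 and control mice was -0.12, with no overlap of the mice (exact permutation p = 0.1, adjusted p = 0.2), where chance gives 10%. Compared within these 4 bins of density, 0.594 times the difference was left (0.569 to 0.639 with 1 mouse left out; exact permutation p = 0.1), so the higher density of clustered sites cannot be told apart from clustering as a source of the rest. For the 251 shared sites on the X chromosome against the 19670 autosomal ones the corresponding difference was 0.028 and the mice overlapped (exact permutation p = 0.3, adjusted p = 0.45).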
